A study of Mus musculus with 4 samples.

How the data were processed

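Single-cell RNA of mouse gingiva was measured in 4 groups, healthy, metformin, disease, and disease plus metformin, with 1 library in each. Per the submitters' processing notes and the file headers, the authors made 10x Genomics libraries, converted the reads with bcl2fastq, and counted them with Cell Ranger 7.0.1 on the mouse genome build mm10. The deposited values were counts, whole numbers of UMIs per gene and called barcode, with no normalization. No other filter by the authors was stated. The lowest UMI total of a deposited barcode was 500. The matrices held 32285 genes under 32245 symbols, and genes under the 40 shared symbols were summed.

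Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept. Scrublet, as built into scanpy, was run per library at an expected rate of 0.8% per 1000 barcodes. It called 5 of 7134 cells (0.0701%), below the 0.5% taken as the least a working caller would mark, so doublet calling has not worked here, and doublets remain among the cells. The called cells were removed, which left 7129. Total UMIs per library ran from 12507787 to 22333858.

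Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes, 30 principal components and 15 neighbours, cells of all libraries were clustered together by the Leiden method at resolution 1. Clusters were named from 22 marker lists. A marker counted as raised in a cluster when it was at least 2-fold above the median over clusters, at least at 10 CPM, and found in at least 10% of cells. A name needed at least 3 raised markers and 25% of a list, with the second class at most at 70% of the first. Among the top 10 genes of the cluster, markers of the class had to be no fewer than those of any other class. A cluster with UMI counts over 3-fold below the library median also needed a marker of the class there. Leukocyte clusters were pooled and clustered again with 10 principal components. Clusters that met no definition stayed unnamed, and all names are written as "-like".

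Shares of cells have exact Clopper-Pearson 95% intervals, and ratios of shares and of counts have conditional exact binomial 95% intervals. For gene levels, raw counts were summed over the cells of a class in a library and given as CPM of that sum, with exact Poisson intervals. All intervals cover counting error only, not differences between mice or between pieces of tissue. Those of gene levels and gene lists treat each UMI as an independent draw. They are therefore too narrow where few cells hold most UMIs of a gene. With 1 library per group, no test across samples could be made, and no p-value, standard error or number of changed genes was given. A gene was measured in a comparison with at least 20 UMIs over the 2 libraries. A count of 0 was set to 3 for a fold, which is then a bound that takes the other count as exact. The counting error of that other count can make the fold smaller. A class was compared with at least 50 cells in both libraries. After seeing the data, classes with at least 20 cells and pooled leukocytes were added.

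Gene lists, 35 in number, were fixed with the marker lists, the comparisons, the naming rule and most alternatives before the data were examined. For each list with at least 3 measured members, the median log2 ratio, its range over 1000 redraws of the counts, the number of members at least 1.5-fold higher or lower, and the percentile of the median among 10000 random lists of equal size, matched in 20 bins of expression, were given. The percentile describes these libraries and is not a test. The metformin effects in healthy and diseased gingiva were compared as a ratio of ratios, and correlations across genes were given only for pairs of comparisons that share no library.

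The named genes of a comparison were the 3 highest and the 3 lowest in each eligible class, ranked by the interval bound nearest 0. They needed at least 50 UMIs, and a CPM in the class at least as high as over all cells, a guard against free RNA. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor, sex-linked and unnamed predicted genes were left out of the ranking. For each list, up to 4 members with the largest bounds were also named. After seeing that single barcodes held most UMIs of some named genes, 6 genes each way were added by the same ranking among genes of which no barcode held over 20% of the UMIs. Positions are from an annotation of GRCm38 and were found for 567 of 568 named genes.

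The procedure was tested on simulated data made from the keratinocyte-like cells of the metformin and healthy libraries. The intervals held the true ratio for 95.7% of 11838 unaltered genes, for 98% of 100 genes set 2-fold apart and for 92% of 100 genes set 4-fold apart. Of 200 unaltered lists of 20 genes, 6% fell outside the central 95% of random lists, and every list set 1.5-fold apart fell above it. The simulated counts were independent Poisson draws, which the intervals assume. The simulation therefore does not show how the procedure does where few cells hold most UMIs of a gene.

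The alternatives were a stricter filter of at least 500 genes and at most 10% mitochondrial UMIs, doublets kept, Leiden resolutions 0.5 and 2, classes by each cell's own marker levels, median-of-ratios size factors, every cell weighted equally, 1 count added, minimum counts of 100 and 1, the mean in place of the median, 10 expression bins, list members at free RNA level left out, and named classes weighted equally. Chosen after seeing the data were removal of the 125 cells with the highest Scrublet scores, leaving out a mixed cluster or counting it as gland, taking cluster profiles of 1 library at the cluster makeup of another, barcodes with at least 1 Malat1 UMI and at least 0.5% mitochondrial UMIs, leaving out the barcode with the most UMIs of a gene, and leukocytes per connective tissue cell. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, umap-learn 0.5.12 and matplotlib 3.10.9.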

Results

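RNA of single cells from mouse gingiva, the gum tissue around the teeth, was counted in droplet libraries of 4 groups. The groups were healthy gingiva, gingiva with metformin, diseased gingiva, and diseased gingiva with metformin. Metformin is a glucose-lowering drug that acts on energy metabolism, and the study asked what it does in the gingiva as a way of preventing periodontal disease. Each group was 1 library, so no replicate check existed for any value, no test was made, and every interval covers counting error only. The number of mice per library, the way disease was induced and the dose of metformin were not given in the sources used here.

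The healthy library held 12507787 UMIs (unique molecular identifiers, each counting 1 RNA molecule) in 1616 barcodes. The metformin library held 22333858 UMIs in 2814 barcodes, the disease library 14151700 in 1972, and the disease plus metformin library 13025479 in 1893. After filtering, 1307 healthy, 2476 metformin, 1692 disease and 1654 disease plus metformin cells were kept. Their median UMI counts were 1877, 1828, 1950.5 and 1715, and their median gene counts were 606, 620, 657.5 and 607, in the same order.

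Most kept cells were keratinocyte-like, the surface epithelium of the gingiva, or salivary gland-like. In the order healthy, metformin, disease and disease plus metformin, keratinocyte-like cells made up 50.5%, 49.3%, 61.1% and 41.1% of cells. Gland-like cells made up 26.8%, 12.0%, 14.8% and 32.0%. In the same order, 46.1%, 47.5%, 30.8% and 58.4% of keratinocyte-like barcodes held no mitochondrial UMI. The selection for Malat1 and mitochondrial RNA, chosen after seeing the data, kept 20.3%, 13.7%, 19.7% and 8.97% of keratinocyte-like barcodes. That selection kept 76.6%, 73.0%, 83.2% and 77.2% of gland-like barcodes. Whether the keratinocyte-like barcodes left out by it were intact cells was not tested. Vascular endothelial-like cells made up 3.44%, 2.58%, 6.38% and 1.75%, and fibroblast-like cells 1.53%, 1.86%, 3.49% and 0.605%. Leukocyte-like cells were 22, 30, 52 and 27 in number. Clusters that met no class definition made up 13.9%, 30.0%, 7.98% and 21.2%. The largest of them, led by Bpifa2, Dcpp1, Dcpp2, Dcpp3 and Dmbt1, all secreted gland products, held 8.34%, 26.2%, 0.118% and 16.3% of cells. It raised 9 gland markers and a share of 0.645 of the keratinocyte markers, and whether it holds gland cells, mixed barcodes or free gland RNA was left open.

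**Figure D1:**
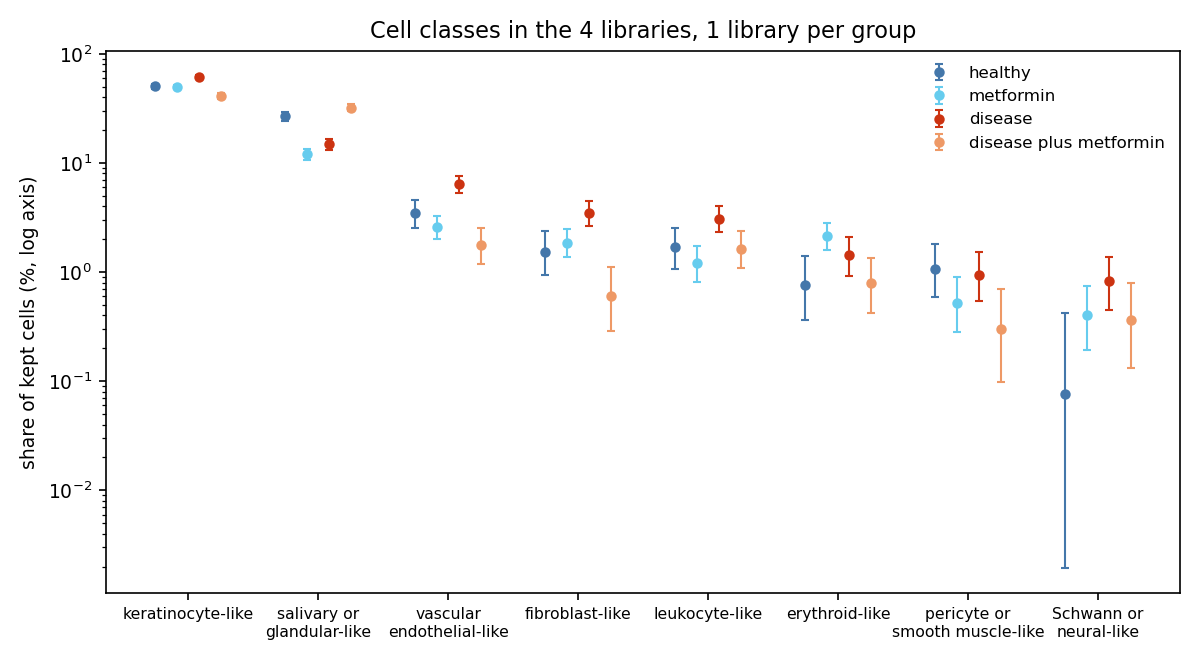
Share of kept cells in each class (percent, log axis) in the 4 libraries, with exact 95% binomial intervals covering counting error only. Leukocyte-like cells made up 1.68% of healthy, 1.21% of metformin, 3.07% of disease and 1.63% of disease plus metformin cells.

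The comparison of disease with healthy gingiva asked what disease looked like in this tissue without the drug. The disease library held more leukocyte-like, endothelial-like and fibroblast-like cells, and higher levels of chemokines, class II antigen-presentation genes, collagens and cell cycle genes. Cxcl2, a chemokine that attracts neutrophils, was at 106 CPM (UMIs per 1000000 UMIs of the library or class) in disease and 21.1 in healthy gingiva, a log2 ratio of 2.32 (95% interval 2.12 to 2.53). H2-Eb1, a chain of the class II complex that presents antigen to helper T cells, was at 69.8 and 7.73 CPM, 9.02-fold higher in disease. Secretory gland genes went the other way, with Dcpp1 at 1215 and 36843 CPM.

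By share of cells, leukocyte-like cells were 3.07% of the disease library (95% interval 2.30% to 4.01%) and 1.68% of the healthy one (1.06% to 2.54%), a log2 ratio of 0.87 (0.12 to 1.66). The log2 ratio was 0.0093 when each cell was assigned by its own marker levels, without clusters, a minimum level or an unnamed class. Neutrophil-like cells were 10 of 1692 in disease and 2 of 1307 in healthy gingiva, with a log2 ratio of 1.95 whose interval ran from −0.28 to 5.18, and of −0.20 with cells assigned by their own marker levels. T cell-like cells were 14 and 3 in number. Log2 share ratios were 1.19 for fibroblast-like (0.32 with cells assigned by their own marker levels), 0.89 for endothelial-like and −0.86 for gland-like cells. That of keratinocyte-like cells was 0.27, and −0.11 with cells assigned by their own marker levels.

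Gene lists were compared over all kept cells, each with the median log2 ratio of its measured members, the 95% range over redrawn counts, and the percentile of that median among 10000 random lists matched on expression. The median of all measured genes was itself 0.15 in this comparison. The inflammatory cytokine and chemokine list had a median of 1.09 (0.87 to 1.31; percentile 100), with 16 of 22 measured members at least 1.5-fold higher in disease and 1 lower. Il1b, the interleukin-1 beta gene, was at 49.0 and 20.0 CPM. Cxcl10, which draws T cells, was 6.94-fold higher, with 61.6% of its disease UMIs in 1 barcode. Ccl5, another T cell chemokine, was at 7.80 CPM against 0 UMIs, at least 28.2-fold higher, with 76.8% of its UMIs in 1 barcode. Here and below, a fold against 0 UMIs sets the 0 to 3 and takes the other count as exact. Among the neutrophil chemoattractants, 5 of 9 members were higher and the median was 1.77 (0.95 to 1.98; percentile 100), or 0.77 among barcodes with Malat1 and mitochondrial RNA. Ccl3 and Ccl6 were 4.20-fold and 3.41-fold higher.

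Antigen presentation by class II was higher in 9 of 10 members, with a median of 1.49 (1.24 to 2.02; percentile 100). Cd74, the invariant chain of class II molecules, was at 297 and 78.2 CPM, and H2-Aa and H2-Ab1 were 4.86-fold and 4.73-fold higher. The class I list had a median of 0.09 (percentile 25.0), and H2-K1, a class I heavy chain, was 1.99-fold lower in disease. In the interferon response list, 13 of 24 members were higher and 1 lower (median 0.68, percentile 100), with the interferon-induced gene Ifi27l2a at 43.4 and 16.8 CPM, and the median was 0.021 over members with at least 100 UMIs. Targets and feedback genes of NF-kB, the main switch of inflammatory transcription, had a median of 0.33 (percentile 98.3). Of these, 9 of 25 were higher, and the adhesion molecule gene Icam1 was 4.24-fold higher. Among genes of alternatively activated macrophages, 6 of 11 were higher and 3 lower (median 0.87, percentile 99.8), and the median was −0.32 with a minimum of 1 UMI and −0.47 with a minimum of 100. Spp1, osteopontin, was at 20.1 CPM against 0.184, a count of 2 UMIs, with a log2 ratio of 6.77 (4.90 to 9.82). Neutrophil granule genes had a median of 0.23 (percentile 77.6), and of −0.57 among barcodes with Malat1 and mitochondrial RNA. Immunoglobulin and plasma cell genes had a median of −0.55 (percentile 0.4), with Igkc at 8.51 and 16.8 CPM.

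Connective tissue genes were higher in disease. Of 26 collagen and matrix genes, 23 were higher and 1 lower (median 1.10, 1.00 to 1.20; percentile 100). Postn, a matrix protein of the periodontal ligament, was 3.37-fold higher, and Col3a1 was at 164 and 64.1 CPM. Matrix-degrading proteases and their inhibitors had a median of 0.63 with 11 of 18 higher (percentile 100), led by Mmp12, macrophage elastase, at 16.4 and 1.66 CPM. Factors that regulate osteoclasts, the cells that resorb bone, had a median of 0.66 with 6 of 10 higher (percentile 99.9), among them Csf1, the macrophage growth factor, 2.62-fold higher. The endothelial activation list had a median of 0.74 with 8 of 11 higher, and the angiogenesis list a median of 1.15 with 6 of 11 higher (both percentile 100). Salivary secretory genes had a median of −0.46 (percentile 0.07), and Bpifa2, a salivary secreted protein, was 24.4-fold lower. These values moved with the larger fibroblast-like and endothelial-like shares and the smaller gland-like share of the disease library.

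Within keratinocyte-like cells (1033 in disease, 660 healthy), cell cycle genes were higher. The cell cycle list had a median of 0.50 (0.35 to 0.60; percentile 100) with 12 of 25 members higher and 1 lower. The class also differed in RNA quality, with no mitochondrial UMI in 30.8% of disease and 46.1% of healthy barcodes. Stmn1, a microtubule regulator, was at 414 and 206 CPM, Ube2c, a mitotic ubiquitin-conjugating enzyme, at 412 and 220, and the replication-dependent histone gene Hist1h3c at 94.2 and 17.4. Krt17, a keratin of stressed and wounded epithelium, was 2.69-fold higher (587 and 218 CPM), and Cxcl14, an epithelial chemokine, 2.04-fold higher. The stress keratin and alarmin list had a median of −0.08 (−0.34 to 0.07) at the cluster makeup of healthy gingiva. Healthy cluster profiles at the disease cluster makeup gave 0.62 (0.28 to 0.70). The cornification list had a median of −0.12 (−0.25 to −0.01; percentile 1.2) with 1 of 18 higher and 6 lower, and a median of 0.19 with cells assigned by their own marker levels and −0.10 (−0.20 to 0.010) at the cluster makeup of healthy gingiva. Krt1 and Krt76, keratins of differentiated layers, were 6.56-fold and 1.90-fold lower, and Tgm1, an enzyme that cross-links the cornified envelope, 2.39-fold lower. Immediate-early genes had a median of −0.44 with 6 of 19 lower (percentile 0), including Dusp1, a phosphatase of stress kinases, at 17.9 and 73.8 CPM. By the naming rule, U90926 (chr5:92209893-92215408, build GRCm38) was highest at 40.1 CPM against 0.217, a count of 1 UMI (log2 ratio 7.53, 5.04 to 12.84), found in 11 disease cells. The muscle genes Tnnc2 and Acta1 came next, with every UMI in 1 barcode. Cyp2t4, found in 7 healthy cells, and Kcnip4 were lowest, 23.2-fold and 16.1-fold lower. Also lower were Per2, a circadian clock gene, 6.08-fold, and Crabp1, a retinoic acid binding protein, 4.41-fold. The hormone subunit gene Gpha2 was 4.02-fold higher.

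Gland-like cells (250 in disease, 350 healthy) had higher heat shock genes, with a median of 0.72 and 8 of 14 members higher (percentile 100), where the median of all genes was 0.14. Hspa5, a chaperone of the endoplasmic reticulum, was at 1255 and 603 CPM. Keratin RNA differed in the same cells, with Krt17 at 414 and 2.94 CPM. Lcn2 and Ltf, antimicrobial iron-binding proteins, were 18.9-fold and 3.61-fold higher, and Cxcl17, a mucosal chemokine, was at 131 and 27.1 CPM. With every cell weighted equally, the Cxcl17 log2 ratio was −0.017. The trefoil peptide gene Tff1 was 9.08-fold higher and Ldhb, a lactate dehydrogenase subunit, 5.42-fold lower. The inflammatory list had a median of 2.16 over 10 measured members, but its leading members came from few cells, with 97.7% of Cxcl3 UMIs in 1 barcode. By the naming rule, Tm4sf1, BC023719 and Psca were highest, with 64.2% of Tm4sf1 UMIs in 1 barcode. BC023719, annotated as an antisense transcript (chr17:36111426-36117121), was at 20.3 CPM against 0 UMIs, at least 32.2-fold higher. Sbpl, Sbp and Crisp1, secreted gland or reproductive tract proteins, were lowest, and 60.2% and 63.6% of the Sbpl and Sbp UMIs came from 1 barcode each. A gland cluster led by Bpifb1, Sbpl and Sbp held 17 healthy and 0 disease cells. Gland cluster 2, led by Spink4 and Wfdc12, was the largest in disease, and gland cluster 4 the largest in healthy gingiva.

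Endothelial-like cells (108 in disease, 45 healthy, below the 50-cell minimum and compared after seeing the data) had higher adhesion, interferon and class I genes, and carried different amounts of RNA of other cell types. The activation list had a median of 1.35 (0.88 to 2.25; percentile 100) with 6 of 8 members higher and none lower, and of 2.63 under the stricter cell filter. Vwf, which binds platelets, was 7.67-fold higher, and the leukocyte-rolling receptor gene Sele was at 178 CPM against 0 UMIs, at least 7.49-fold higher. B2m, the light chain of class I, was at 1256 and 388 CPM, and 6 of 9 class I genes were higher (median 0.79, percentile 100), as were 8 of 9 interferon genes (median 0.91, percentile 100). Lowest in these cells were the keratin genes Krt13, at 65.2 and 2814 CPM with 56.9% of the healthy UMIs in 1 barcode, and Krt4, at 39.1 and 1482 with 61.5% in 1 barcode. Mmrn1, a gene of lymphatic endothelium, was at 65.2 and 1062 CPM, with 70.9% of the healthy UMIs in 1 barcode. In pooled leukocyte-like cells, class II genes had a median of 1.67 with 7 of 9 higher (percentile 100), or 0.88 with every cell weighted equally, led by H2-Eb1 at 3315 and 517 CPM. The pooled class differed in makeup, since the cluster led by H2-Eb1 held 12 of 52 disease and 1 of 22 healthy cells, and B cell-like cells were 6 and 10.

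The comparison of disease plus metformin with disease asked whether gingiva given the drug had less of the disease pattern. Chemokine, class II, granule, collagen and cell cycle genes were lower with metformin, while interferon and immediate-early genes were higher. Il1b was at 18.2 and 49.0 CPM, 2.69-fold lower with metformin, and Cxcl2 at 41.5 and 106, 2.54-fold lower. S100a8 and S100a9, the calprotectin subunits that fill neutrophils, were at 2.25 against 334 and 0.834 against 452 CPM. The gland share was 32.0% with metformin and 14.8% without, and connective tissue cells were fewer.

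Leukocyte-like cells were 1.63% of the disease plus metformin library (1.08% to 2.37%) and 3.07% of the disease library, a log2 ratio of −0.91 (−1.64 to −0.22). It was 0.040 with cells assigned by their own marker levels, and 1.11 (0.29 to 1.93) when leukocytes were counted per fibroblast-like, vessel-like and pericyte-like cell, a count chosen after seeing the data. Neutrophil-like cells were 0 of 1654, with a 95% interval up to 0.223%, against 10 of 1692, or 3.26-fold lower with 3 cells in place of 0. A further leukocyte cluster, led by Ngp and Camp and left unresolved with 14 raised neutrophil markers, held 2 and 3 cells, which the count of 0 does not include. Ngp had no UMI in the kept disease plus metformin cells, so whether those 2 cells are neutrophils stays open. With cells assigned by their own marker levels the log2 ratio of the neutrophil-like share was −0.0090. Log2 share ratios were −2.53 (−3.66 to −1.55) for fibroblast-like (−0.79 with cells assigned by their own marker levels), −1.86 (−2.51 to −1.26) for endothelial-like and 1.12 (0.90 to 1.34) for gland-like cells (2.08 with cells assigned by their own marker levels).

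Over all cells the median of all measured genes was −0.24. The inflammatory list had a median of −1.24 (−1.44 to −0.998; percentile 0), with 17 of 24 members lower and 3 higher. Its median was −0.55 with keratinocyte-like and gland-like cells weighted equally, the only named classes with at least 50 cells in every library. That value holds no leukocyte, vessel or fibroblast cells. Cxcl10 was 5.74-fold lower, and Ccl8, a monocyte chemokine, was at 0 UMIs against 3.31 CPM, at least 13.2-fold lower. Il17a, the cytokine of type 17 T cells, was at 1.92 CPM against 0 UMIs, with every UMI in 1 barcode. Neutrophil chemoattractants had a median of −0.72 with 5 of 10 lower and 2 higher (percentile 4.4), and of −0.13 among barcodes with Malat1 and mitochondrial RNA. Of the NF-kB genes, 9 of 24 were lower and 1 higher (median −0.28, percentile 35.4). Tnfaip2, an NF-kB target, was 3.70-fold lower. Class II genes were lower in 8 of 10 members and higher in none (median −0.96, percentile 0.06), with H2-Eb1 at 5.67 and 69.8 CPM and Cd74 at 138 and 297. Of 14 granule genes, 10 were lower and 2 higher (median −1.02, percentile 0). Ngp, a neutrophil granule protein, was at 0 UMIs against 85.5 CPM, at least 342-fold lower, with 60.7% of the disease UMIs in 1 barcode.

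Collagens and matrix genes had the lowest median of this comparison over all cells apart from muscle genes (−2.87), −2.20 (−2.43 to −1.99; percentile 0), with 23 of 26 lower and 1 higher. Col1a1, the main fibrillar collagen gene, was at 4.09 and 60.4 CPM, and Col3a1 at 14.9 and 164. Proteases had a median of −0.76 with 9 of 16 lower and none higher (percentile 0), and Mmp12 was 19.6-fold lower. Osteoclast-regulating factors had a median of −0.07 (percentile 87.1), and of −0.71 with a minimum of 100 UMIs. Salivary secretory genes had a median of 1.08 (percentile 100), with the gland mucin gene Muc5b at 42544 and 21689 CPM. The lower connective tissue genes and the higher gland genes moved with the cell shares.

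The interferon list was higher in 14 of 27 members and lower in 5 (median 0.62, 0.38 to 0.74; percentile 100). Zbp1, a sensor of viral nucleic acid, was at 12.1 and 3.78 CPM. Class I genes had a median of 0.16 (percentile 99.1), and H2-K1 was at 375 and 160 CPM. Immediate-early genes, which respond within minutes to stress and to tissue dissociation, had a median of 0.60 with 11 of 22 higher and 3 lower (percentile 100), including Nr4a1 at 79.2 and 27.3 CPM and Atf3 at 235 and 90.8. Immunoglobulin genes had a median of 0.77 with 7 of 10 higher (percentile 100), and 82.7% of the Igkc UMIs came from 1 barcode. The immunoglobulin median was −0.55 with every cell weighted equally.

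Within keratinocyte-like cells (680 with metformin, 1033 without), cell cycle genes had a median of −0.42 (−0.49 to −0.31; percentile 0), with 7 of 25 lower and none higher, where the median of all genes was −0.13. The class differed in makeup, with 44 and 142 cells in its cluster of most UMIs per cell, and in RNA quality, with no mitochondrial UMI in 58.4% and 30.8% of barcodes. At the cluster makeup of disease, an alternative chosen after seeing the data, the cell cycle median was −0.32 (−0.42 to −0.24). Top2a, which untangles DNA in dividing cells, was at 176 and 319 CPM, and Mki67, a proliferation marker, at 130 and 218. Cornification genes had a median of −0.56 with 8 of 18 lower and 2 higher (percentile 0). Krt4, a keratin of soft mucosa, was at 292 and 1608 CPM, while Krt76, of hard palate and gingiva, was at 838 and 249 and Krt1 was 13.4-fold higher. Krt15, a keratin of basal cells, was 2.35-fold higher (993 and 423 CPM). Stress keratins and epithelial alarmins had a median of −0.77 with 8 of 15 lower and 3 higher (percentile 0), and S100a8 was 4.30-fold lower, with 57.9% of its disease UMIs in 1 barcode. Krt17 was not lower, at 879 and 587 CPM. Il1rn, the interleukin-1 receptor antagonist, was 2.16-fold lower. By the naming rule Krt1, Sncg, a synuclein, and Kcnip4 were highest, with Sncg at 59.4 and 5.90 CPM, and Pcdh9, a cell adhesion protein, was lowest, 38.9-fold. Thsd4 and Paqr5 were 2.84-fold and 2.83-fold lower, and the Thsd4 log2 ratio was 1.32 with cells assigned by their own marker levels.

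Gland-like cells (530 with metformin, 250 without) had higher interferon and immediate-early genes, while the keratin gene Krt17 was at 31.4 and 414 CPM in them. The interferon list had a median of 1.57 (0.81 to 1.64; percentile 100) with 11 of 17 higher and none lower, and a median of 0.93 over members with at least 100 UMIs. Irf1, an interferon-induced transcription factor, was at 56.4 and 18.9 CPM, and Isg15, a ubiquitin-like antiviral protein, at 16.7 and 4.34. Immediate-early genes had a median of 0.90 with 14 of 20 higher and 1 lower (percentile 100). Socs3, a brake on cytokine signalling, was 4.37-fold higher, and Nr4a1 was 3.34-fold higher. Of 12 class I genes 4 were higher and 1 lower (median 0.23, percentile 99.5), with H2-K1 and H2-D1, class I heavy chains, 2.23-fold and 1.72-fold higher. Itln1, a lectin that binds microbial sugars, was at 64.3 and 9.36 CPM, and Lbp, which binds bacterial lipopolysaccharide, at 55.2 and 9.13. Iqcg was highest by the naming rule, at 21.1 CPM against 0.685, a count of 3 UMIs (log2 ratio 4.95, 3.37 to 7.24). Fgb, a fibrinogen chain, was 23.1-fold higher. Psca was at 0 UMIs against 167 CPM, which came from 7 disease cells, and Amhr2, a hormone receptor, was at 0.142 CPM, a count of 1 UMI, against 21.0. Gdf15, a stress-induced cytokine, was 23.4-fold lower, with 75.9% of its disease UMIs in 1 barcode. Gland cluster 4 was the largest with metformin and cluster 2 without.

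Endothelial-like cells were 29 with metformin and 108 without, a comparison added after seeing the data. Their immediate-early genes were lower in 11 of 15 members and higher in none (median −0.82, percentile 0), the opposite direction to gland-like cells, with Fos at 172 and 956 CPM. Their activation list had a median of −0.50 (percentile 1.0). Of these endothelial-like barcodes, 34.5% with metformin and 4.63% without had no mitochondrial UMI. Of lymphatic marker genes, Ccl21a had a log2 ratio of −5.93 and Reln of 2.36 in them. In pooled leukocyte-like cells (27 and 52), the inflammatory list had a median of −0.78 (−0.90 to −0.36; percentile 0.01) with 9 of 17 lower and 4 higher, and Il1b was at 1286 and 2415 CPM. The pooled class differed in makeup, since neutrophil-like cells, in a cluster led by Il1b and Cxcl2, were 0 of 27 and 10 of 52, and T cell-like cells 11 and 14.

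The comparison of metformin with healthy gingiva asked what the drug did without disease. Mitochondrially encoded respiratory chain genes were lower in the metformin library in both large classes, and 6 of 25 glycolysis and hypoxia genes were higher over all cells. In keratinocyte-like cells mt-Co2, a subunit of cytochrome c oxidase, was 1.73-fold lower and Eno1, a glycolytic enzyme, was at 116 and 62.7 CPM. Several chemokines and class II genes were also higher, the direction seen in disease, with Cxcl2 at 84.1 and 21.1 CPM and Il1b at 56.0 and 20.0. Gland-like cells were 12.0% of the metformin library (10.7% to 13.3%) and 26.8% of the healthy one (24.4% to 29.3%). With the largest unnamed cluster counted as gland, a count made after seeing the data, they were 944 of 2476 and 459 of 1307, a log2 ratio of 0.12 (−0.044 to 0.28).

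Leukocyte-like cells were 1.21% (0.819% to 1.73%) and 1.68%, a log2 ratio of −0.47 whose interval ran from −1.32 to 0.39, so that no difference was detectable at this number of cells. Neutrophil-like cells were 5 and 2 in number (log2 ratio 0.40, −2.21 to 3.79), and B cell-like cells 3 and 10 (−2.66, −5.16 to −0.70). The gland log2 share ratio was −1.16 (−1.39 to −0.94), −0.26 at the finer clustering resolution of 2, and 0.14 with cells assigned by their own marker levels. Erythroid-like cells were 2.14% and 0.765%, and haemoglobin genes moved with them (median 1.59, percentile 100, or 4.39 among barcodes with Malat1 and mitochondrial RNA).

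Over all cells the inflammatory list had a median of 0.33 (0.16 to 0.68; percentile 99.9) with 8 of 21 members higher and 1 lower. Its median was 0.020 with keratinocyte-like and gland-like cells alone weighted equally and 0.036 with every cell weighted equally. Neutrophil chemoattractants had a median of 0.82 with 5 of 8 higher (percentile 100), or 0.22 among barcodes with Malat1 and mitochondrial RNA, and Ccl3 was 5.15-fold higher. Class II genes were higher in 6 of 9 members (median 0.72, percentile 100), with H2-Eb1 at 35.3 and 7.73 CPM. Granule genes had a median of −0.89 with 7 of 14 lower (percentile 0), or −1.63 among barcodes with Malat1 and mitochondrial RNA, but Ngp and Camp, antimicrobial granule proteins, came from 2 healthy cells each. Immunoglobulin genes had a median of −1.08 with 5 of 7 lower and none higher (percentile 0.03), or −1.78 with every cell weighted equally. Collagens had a median of 0.56 with 12 of 26 higher (percentile 100), and cell cycle genes a median of 0.50 with 11 of 25 higher (percentile 100). The interferon list had a median of 0.39 (percentile 100), and −0.12 with every cell weighted equally.

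Energy genes separated by genome. Mitochondrially encoded genes had a median of −0.64 in keratinocyte-like cells (−0.67 to −0.59; percentile 0), with 8 of 13 lower, and of −0.64 in gland-like cells (−0.66 to −0.60; percentile 0), with 8 of 13 lower. Among barcodes with at least 1 Malat1 UMI and at least 0.5% mitochondrial UMIs, a selection chosen after seeing the data, the keratinocyte median was −0.31 and the gland median −0.69. With metformin cluster profiles taken at the healthy number of cells per cluster, also chosen after seeing the data, both were −0.40. In disease plus metformin over disease the median was −0.31 (−0.33 to −0.22; percentile 0) in keratinocyte-like cells, −0.97 with every cell weighted equally and 0.0043 among the selected barcodes, and it was 0.049 in gland-like cells. Mitochondrially encoded genes made up 2.57% of keratinocyte UMIs with metformin and 3.97% without, and 3.11% and 4.60% of gland UMIs. The healthy library had the highest percent of all 4 in both classes, and without the drug disease over healthy also had medians of −0.29 in keratinocyte-like and −0.23 in gland-like cells. That gland median was 0.18 with cells assigned by their own marker levels. Nuclear-encoded genes of complex I, the respiratory complex that metformin is known to inhibit, had medians of 0.12 in keratinocyte-like cells (percentile 76.4) and 0.32 in gland-like cells (percentile 89.0), and complexes III to V of 0.16 and 0.39. In endothelial-like cells the mitochondrially encoded median was 0.41. Glycolysis and hypoxia genes had a median of 0.36 over all cells (0.28 to 0.39; percentile 100) with 6 of 25 higher and none lower, and of 0.12 in keratinocyte-like cells. The AMPK list, subunits and targets of the energy-sensing kinase that metformin activates, had a median of −0.31 in keratinocyte-like cells (percentile 38.5), where the median of all genes was −0.23. Acaca, the first enzyme of fatty acid synthesis, was at 45.8 and 85.3 CPM there, and Rptor, a subunit of the growth-controlling kinase complex mTORC1, at 32.0 and 55.2. The keratinocyte-like cluster of most UMIs per cell held 90 of 1220 metformin and 83 of 660 healthy cells. Levels of Acaca and Rptor at equal cluster makeup were not computed, so makeup may carry part of these differences. The integrated stress response had a median of 0.00 over all cells (percentile 68.4) and the NRF2 antioxidant list 0.17 (percentile 86.8).

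Keratinocyte-like cells (1220 with metformin, 660 healthy) had basal and hemidesmosome genes with a median of −0.34 (percentile 1.7). With cells assigned by their own marker levels the basal list median was 0.083, and at the cluster makeup of healthy gingiva it was −0.12. Trp63, the master regulator of stratified epithelium, was 1.64-fold lower. The class differed in makeup, with 90 and 83 cells in its cluster of most UMIs per cell. Trp63 alone was not computed at equal makeup. Among cornification genes 6 of 17 were higher and 3 lower (median 0.09, percentile 88.8), including Krtdap, a protein of differentiating keratinocytes, at 4826 and 2530 CPM. Krt17 was 3.52-fold higher (768 and 218 CPM), and Spink5, a protease inhibitor of the epithelial barrier, 3.38-fold higher. The stress keratin and alarmin list, which holds Krt17, had a median of −0.24 over 12 members measured in both metformin comparisons. At the cluster makeup of healthy gingiva it was −0.50 (−0.87 to −0.40). Healthy cluster profiles at the metformin cluster makeup gave 0.88 (0.68 to 1.06). AA465934, a processed transcript (chr11:83291699-83294632), and Dynlt1f were highest by the naming rule, 7.45-fold and 6.37-fold. Cyp2t4 and Psca were lowest, 58.9-fold and 47.9-fold, each with its healthy UMIs in 7 cells, and 94.8% of the healthy UMIs of Lyg1, also among the lowest, came from 1 barcode. Per2 was 18.5-fold lower, Crabp1 18.1-fold, Gprasp1 10.9-fold and Dusp1 5.50-fold. Ptgs2, the inducible prostaglandin synthase, was at 0.490 and 9.34 CPM.

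Gland-like cells (296 with metformin, 350 healthy) had higher ribosomal protein genes, with 20 of 35 higher (median 0.59 against 0.15 for all genes, percentile 100), and higher heat shock genes (median 0.40, percentile 98.6), with Hspa5 at 1113 and 603 CPM. Cell cycle and keratinocyte lists were further apart in the same cells, with medians of 4.04 for cell cycle, 2.11 for stress keratin and 1.92 for basal keratinocyte genes. BC018473, annotated as an antisense transcript (chr11:116752167-116759373), was at 53.9 CPM against 0 UMIs, at least 85.4-fold higher, and BC023719 at 24.1 CPM against 0, at least 38.2-fold higher. Itln1 was at 50.4 CPM against 0.631, a count of 3 UMIs (log2 ratio 6.32, 4.76 to 8.61). Bpifb1, a secreted airway and gland protein, was 61.1-fold lower, with 57.3% of its healthy UMIs in 1 barcode. Ldhb was 15.1-fold lower, and Smgc, a product of neonatal and sublingual glands, was at 1872 and 4404 CPM. Gland cluster 2 was the largest with metformin and cluster 4 in healthy gingiva. In pooled leukocyte-like cells (30 and 22), the inflammatory list was higher in 10 of 14 members and lower in 1 (median 1.53, percentile 100), and 16 of 19 NF-kB genes were higher (median 0.97). These pools differed in makeup, with 3 and 10 B cell-like and 15 and 4 unresolved cells. Endothelial-like cells (64 and 45) had an activation list median of 0.79 (percentile 99.9), or 2.39 under the stricter cell filter, and Esm1, a marker of sprouting vessels, was 8.54-fold higher. The keratin genes Krt13 and Krt4 were at 128 and 33.1 CPM in them with metformin, against 2814 and 1482 in healthy gingiva. Single barcodes held 56.9% and 61.5% of those healthy UMIs. The leukocyte and endothelial comparisons were added after seeing the data.

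**Figure D2:**
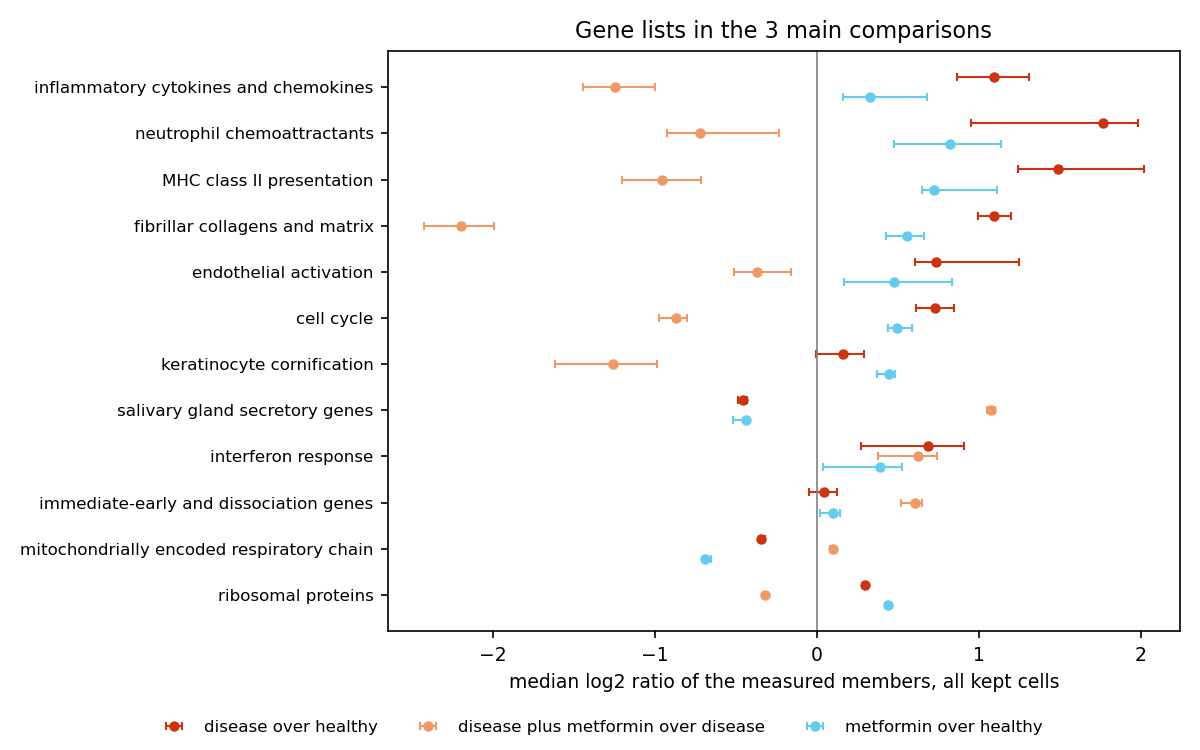
Median log2 ratio of the measured members of 12 gene lists over all kept cells (points), with 95% ranges over redrawn counts (bars), in the 3 main comparisons. Collagens and matrix genes sit at 1.10 for disease over healthy, −2.20 for disease plus metformin over disease and 0.56 for metformin over healthy.

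The effect of metformin was set side by side in healthy and in diseased gingiva, since these ratios share no library. Across 14082 genes over all cells the log2 ratios had a Pearson correlation of −0.23, and the values were 0.15 in keratinocyte-like cells (0.27 over genes with at least 100 UMIs) and −0.15 in gland-like cells. The keratinocyte-like cluster of most UMIs per cell was a smaller part of the class in both metformin libraries. It held 83 of 660 healthy, 90 of 1220 metformin, 142 of 1033 disease and 44 of 680 disease plus metformin cells. Its part in the keratinocyte correlation was not tested. The disease ratios without and with metformin, disease over healthy and disease plus metformin over metformin, also share no library. Their Pearson correlation was −0.21 over all cells (14101 genes), −0.053 in keratinocyte-like and −0.14 in gland-like cells. Genes higher in disease without metformin were thus not in general higher in disease with it. Genes are not independent replicates, so no p-value was given. The ratio of the metformin ratios, disease over healthy, was −0.44 (−1.48 to 0.60) in log2 for the leukocyte share, an interval that held 0. It was −2.81 (−4.04 to −1.58) for the fibroblast share and 2.28 (1.97 to 2.59) for the gland share. For the inflammatory list its median over 20 members was −1.66, for collagens −2.43 and for the interferon list 0.27.

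Disease plus metformin was also set against healthy gingiva, as values only. The inflammatory list had a median of 0.15 with 6 of 20 members higher and 4 lower (percentile 97.3). Class II genes had a median of 0.72, interferon genes 0.71 and immediate-early genes 0.71 (each percentile 100). Collagens had a median of −1.07 and cornification genes −1.05 (both percentile 0).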

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

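The tests by leukocytes per connective tissue cell, by the unnamed cluster as gland and by the makeup of classes other than leukocytes were chosen after the result was seen, and the test by the makeup of all classes was planned. Each value here was picked out because metformin went with opposite directions in diseased and in healthy gingiva, and with 1 library per group none of these differences was tested.

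In log2, disease plus metformin over disease against metformin over healthy, the gland-like share was 1.12 against −1.16. The opposite direction of the gland share was absent with the largest unnamed cluster counted as gland (1.70 against 0.12) and with cells assigned by their own marker levels (2.08 against 0.14), and whether that cluster is gland, mixed barcodes or free gland RNA is not settled. Over all cells, the inflammatory list median was −1.24 against 0.33, the class II list −0.96 against 0.72, and the glycolysis and hypoxia list −0.48 against 0.36. For the inflammatory list the value in metformin over healthy was near 0 with keratinocyte-like and gland-like cells alone weighted equally (0.020). It was also near 0 with every cell weighted equally (0.036). Collagens were at −2.20 against 0.56 and immunoglobulin genes at 0.77 against −1.08. With every cell weighted equally the immunoglobulin medians were −0.55 against −1.78, the same direction, and 82.7% of the Igkc UMIs in disease plus metformin came from 1 barcode. Cell cycle genes were at −0.87 against 0.50, the senescence and secretory list at −0.80 against 0.41, and ribosomal protein genes at −0.32 against 0.44. Haemoglobin genes were at −1.07 against 1.59, but at 1.65 against 2.497, the same direction, under the stricter filter. Salivary secretory genes were at 1.08 against −0.44.

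The lower leukocyte share and lower inflammatory list in disease plus metformin than in disease could come from the piece of tissue taken, since the 4 libraries differed in gland, vessel and fibroblast content. For the inflammatory list, the makeup of the classes other than leukocytes was argued against as the whole cause. The piece of tissue was not, because that test held the leukocyte share, which may itself follow the piece. With the leukocyte share held and the other classes in the disease plus metformin proportions, the disease profiles gave a median of −0.22 (−0.48 to −0.19), against −1.24 observed, and for disease over healthy 0.28 (0.10 to 0.48), against 1.09. With the leukocyte classes in the mixture too, class makeup gave −0.86 (−1.08 to −0.77), 68.9% of the observed median, and 0.92 (0.65 to 1.09), 84.2%, so most of the list could follow the number and kind of leukocytes. The healthy profiles rested on 2 neutrophil-like, 3 T cell-like and 3 macrophage-like cells, and the ranges redraw UMIs, not cells. The unresolved class pooled the clusters led by Ngp and by H2-Eb1, with 3 and 1 healthy and 3 and 12 disease cells. For the leukocyte share, and for the list through it, the piece of tissue cannot be told apart from another cause. Leukocytes per fibroblast-like, vessel-like and pericyte-like cell were higher with metformin (log2 ratio 1.11, 0.29 to 1.93, from 27 per 44 against 52 per 183 cells), so that connective tissue was lower by more than leukocytes were. For disease over healthy that ratio was 0.029 (−0.78 to 0.84), so the higher leukocyte share there may follow connective tissue content. An effect of disease or of metformin on the tissue stays open and was not tested, because group and piece of tissue were the same thing here.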

How the results depend on the processing

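Alternatives chosen after seeing the data were barcodes with Malat1 and mitochondrial RNA, leukocytes per connective tissue cell, the top barcode left out, the mixed cluster left out or counted as gland and doublet scores by rank. Direction was kept in 1356 of 1433 recomputed list medians (149 results), 1246 of 1250 named gene ratios (162 results) and 222 of 239 share ratios (30 results). Named genes were picked from these data for ratios far from 0, so their direction was likely to be kept. The totals also pool alternatives that changed little, such as doublets kept. Assigning cells by their own markers kept direction in 43 of 54 list medians and 20 of 30 share ratios. Fewer values stayed within the range or interval of the main result, at 1083 of 1433 list medians, 1065 of 1250 named gene ratios and 211 of 239 share ratios. For list medians this depended on the alternative. It was 149 of 149 with 1 count added, but 77 of 149 with median-of-ratios size factors. It was 58 of 149 with every cell weighted equally and 24 of 54 with cells assigned by their own markers. Of list percentiles, 268 of 298 stayed within their range. Where a value below differed, the cause was not tested. With classes by each cell's own markers, log2 share ratios were 0.0093 for leukocytes (disease over healthy), 0.040 for leukocytes and −0.0090 for neutrophils (disease plus metformin over disease), −0.11 for keratinocytes (disease over healthy) and 0.14 for gland (metformin over healthy), which was 0.12 with the mixed cluster counted as gland. List medians were then 0.19 for cornification in keratinocytes and 0.18 for mitochondrially encoded genes in gland (both disease over healthy). In metformin over healthy they were 0.083 for basal genes in keratinocytes, 0.12 for collagens in fibroblasts and 0.15 for immediate-early genes in endothelium. Gpnmb in fibroblasts was at 0.39 in disease over healthy, and Thsd4 in keratinocytes at 1.32 in disease plus metformin over disease. Per connective tissue cell, leukocyte ratios were 0.029 in disease over healthy and 1.11 in disease plus metformin over disease. Among barcodes with Malat1 and mitochondrial RNA, the neutrophil ratio was −0.29 in disease over healthy, with no value in the other comparisons. The inflammatory medians were 0.76, −0.79 and 0.14 for disease over healthy, disease plus metformin over disease and metformin over healthy. Muscle genes were at −0.093 (disease over healthy) and mitochondrially encoded genes in keratinocytes at 0.0043 (disease plus metformin over disease), which were at −0.31 over all barcodes and −0.97 with every cell weighted equally. With keratinocyte-like and gland-like cells alone weighted equally, the inflammatory medians were 0.84, −0.55 and 0.020 for disease over healthy, disease plus metformin over disease and metformin over healthy. A minimum of 100 UMIs gave 0.82 in disease over healthy. With every cell weighted equally, inflammatory medians were −1.56 in disease plus metformin over disease and 0.036 in metformin over healthy. Immunoglobulin genes were at −0.55 in disease plus metformin over disease, interferon genes at −0.12 in metformin over healthy, and Cxcl17 in gland at −0.017. Under the stricter filter, haemoglobin was at −1.13 in disease over healthy and 1.65 in disease plus metformin over disease, where it was 5.04 in keratinocytes. The mean of members put fibroblast collagens at 0.084 (metformin over healthy), and Lyg1 in keratinocytes was at 1.28 without its top barcode in disease over healthy.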

Other observations

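All tests in this part on barcodes with mitochondrial RNA, on cluster makeup, on metformin with and without disease, and on inherited differences were chosen after the results were seen. Some genes of the circadian clock, looked at after Per2 appeared among the named genes and picked from a table of 15 without a test, stood apart between the libraries in keratinocyte-like cells. Per2, a repressor of the clock, was at 21.7 CPM in healthy, 1.18 in metformin, 3.57 in disease and 5.47 in disease plus metformin cells. Nr1d1, another clock repressor, was at 2.17, 4.61, 7.30 and 11.2 CPM in the same order, and its relative Nr1d2 at 5.86, 4.51, 9.48 and 15.3. Hlf, a clock output gene, was at 26.1, 9.11, 10.9 and 7.39 CPM. Others were closer, with Clock at 150, 123, 171 and 132 CPM and Arntl at 76.6, 51.7, 80.8 and 55.5. In gland-like cells Nr1d1 was at 0.841, 1.32, 1.37 and 9.92 CPM and Hlf at 0.841, 0.826, 1.14 and 0.425. The time of day of sampling was not given in the sources used here.

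Fibroblast-like cells were 20 healthy, 46 metformin, 59 disease and 10 disease plus metformin. In disease over healthy, NF-kB genes had a median of 0.65 in them with 7 of 11 higher and none lower (percentile 99.8). Cxcl1, a neutrophil chemokine, was at 309 CPM against 0 UMIs, at least 12.7-fold higher, with 47.9% of its UMIs in 1 barcode. In metformin over healthy, Adm, a vessel-dilating peptide, was 10.9-fold higher and collagens had a median of −0.18 (percentile 0.7), but of 0.12 with cells assigned by their own marker levels and 0.084 as the mean of the members. Schwann-like cells, the glia of peripheral nerve, were 1, 10, 14 and 6 in the order healthy, metformin, disease and disease plus metformin.

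Metformin is known to act on mitochondria, and a candidate explanation for the lower mitochondrially encoded genes in metformin over healthy is an effect of the drug. Scaling was argued against as the whole cause, since median-of-ratios size factors left medians of −0.42 (−0.45 to −0.37) in keratinocyte-like and −0.79 (−0.80 to −0.74) in gland-like cells. Barcodes with little mitochondrial RNA were argued against in gland-like cells, where the median among barcodes with Malat1 and mitochondrial RNA was −0.69 (−0.70 to −0.64). In keratinocyte-like cells it was −0.31 (−0.35 to −0.26) against −0.64, a range that held 0.5 of the observed size, so that this explanation and another cause cannot be told apart. The selection is itself made on mitochondrial UMIs, so that it can also remove an effect of the drug. Cluster makeup alone gave −0.15 (−0.17 to −0.13) in keratinocyte-like cells, which argues against it as the whole cause there. In gland-like cells it gave −0.31 (−0.33 to −0.30), a range that held 0.5 of the observed −0.64, so that cluster makeup and another cause cannot be told apart. Whether these genes are also lower with metformin in disease cannot be told apart from cluster makeup. In disease plus metformin over disease the keratinocyte median was −0.31 (−0.33 to −0.22), but 0.017 (−0.0052 to 0.11) at the cluster makeup of disease. The gland median was 0.049 (0.019 to 0.064), but −0.16 (−0.17 to −0.087) at that makeup. The clusters were made in part from these genes, so that holding makeup fixed can also remove an effect of the drug. The same genes were also lower in disease over healthy, without the drug (−0.29 and −0.23), so that a healthy library standing apart stays open beside a drug effect in healthy tissue alone or with disease too. The gland value there was 0.18, the other direction, with cells assigned by their own marker levels.

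A further pattern was 17 cases, over 14 genes of 9998 measured, in which a gene stood at least 2-fold apart in 1 library from the other 3 pooled, though not always from each of them, in keratinocyte-like, gland-like and remaining cells alike. Free RNA from 1 cell type may account for most of them, since the median of the lowest over the highest CPM of the 3 cell groups was 0.0165 (0.0138 to 0.0181). Dcpp1, a gland product, was at 369, 320, 5.44 and 334 CPM in keratinocyte-like cells, in the order healthy, metformin, disease and disease plus metformin. Among the 5 with levels within 10-fold over the cell groups, Krt17 and Psca were the least even, with lowest over highest ratios of 0.181 and 0.129. In keratinocyte-like cells BC023719 was at 0.217, 10.0, 7.92 and 9.85 CPM, AA465934 at 2.61, 19.4, 4.04 and 14.5, and Gprasp1 at 28.9, 2.65, 22.1 and 25.4. Inherited differences between the mice cannot be told apart from other causes for these, since 0 of the 5 had a neighbour within 5000000 bases and random draws also gave a median of 0. Of all 17 cases, 4 had such a neighbour. They were Dcpp1, Dcpp2, Dcpp3 and Sbpl, lower in disease, and were left out of that count because their levels were not within 10-fold over the cell groups.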
